A study of Homo sapiens with 3 samples.

How the data were processed

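Small RNA was sequenced from 3 HEK-293T cultures, 1 library each from wild type cells, cells with Cas9 and an sgRNA from the U6 promoter, and cells with Cas9 and an sgRNA from a glutamine tRNA. Per the labels' protocols, cells grew with 10% serum, and 1 ug/ml puromycin was named for samples given by number, read here as the transduced lines. RNA of 50 to 140 nt was cut from a gel, dephosphorylated and rephosphorylated to leave a single 5′ phosphate, and made into TruSeq small RNA libraries. cDNA of about 170 to 240 bp was selected and sequenced as single 50-nt reads. The dephosphorylation lets fragments with other ends ligate, and base modifications of tRNAs can stop reverse transcription, so reads per family depend on structure and modification as well as on abundance.

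Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, to a set of named small RNA features. The deposited files hold 1 row per distinct aligned sequence, with the feature, the first and last aligned base and a value in RPM, reads scaled by the authors to 1000000 of a library total. The reference set, the adapter trimming, the allowed mismatches, the handling of reads that match several features and the total used for scaling are not given in the sources used here. In each file 100% of RPM values were whole multiples of the lowest value, within a tolerance of 0.1 read, so whole reads were recovered by dividing by that value (0.301, 0.284 and 0.350 RPM per read in the wild type, U6 and tRNAGln libraries). Implied library totals were 3322815, 3521329 and 2859315 reads. The files held 74112, 60568 and 48342 rows, and all alignments lay on the plus strand and spanned 15 to 50 nt. Positions are counted from 1 on each feature. Features carry no genome position here, and genome coordinates were not used.

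Features labelled as tRNA were summed into families by amino acid and anticodon. Labels with an unknown amino acid, suppressor or pseudogene were kept as families of their own. The measure was reads scaled to 1000000 reads on tRNA features. The plan had assumed read counts, and the recovered reads took their place. With 1 library per group no count model could be fitted, so the number of families it calls cannot be given. Ratios carry exact binomial (Clopper-Pearson) 95% intervals conditional on the sum of both counts, for counting error only. Their median width on the log2 scale was 0.20 for the tRNAGln against the U6 library. A fixed rule of size was used in place of a test, a log2 ratio of at least 1 in size with at least 100 reads over the 2 libraries. In data simulated from the libraries' own family levels (20 simulations per comparison), the intervals for tRNAGln against U6 held the true value in 93% of families changed 4-fold, 96% of those changed 1.5-fold and 95.4% of unchanged families. All 4-fold changes and none of the others passed the rule. The simulated libraries held counting error only, without variation between libraries or in read placement. They therefore cannot show how often the rule calls unchanged families in real libraries.

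The families named for the tRNAGln against U6 comparison are the 10 highest and 10 lowest log2 ratios, the glutamine families and the 5 most abundant families of each library. For the other pairs they are the 5 highest, the 5 lowest and the glutamine families. Single features are named for glutamine. Lists of families were the glutamine, glutamate, long variable arm and intron-containing families, the families of each amino acid, other RNA polymerase III transcripts, and small RNAs made by RNA polymerase II. A list's median was set among 10000 random lists of the same size matched on mean level, except for the polymerase II list, which holds most of the labels such lists would be drawn from. Lists for initiator methionine and mitochondrial tRNAs had no members, and selenocysteine had 1 read. Methionine features were labelled CAT without a split into initiator and elongator. Intervals of medians came from 2000 resamplings of families, and Pearson's r and Spearman's rho were taken over log2 levels.

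These rules, the lists and most alternatives were fixed before the data were examined. The alternatives were median-of-ratios factors, trimmed means of M-values (edgeR 4.0.16 in R 4.3.3), all listed reads as the total, minimums of 10, 1000 and no reads, each distinct sequence counted once, reads of at least 30 nt, single features, a rule of 1.5-fold and a total without Leu-CAG. Added after seeing the data were amino acid sums, the authors' library totals, each family without its largest sequence in each library, and reads over 16 nt. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.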

Results

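The series measured small RNAs, mainly transfer RNAs (tRNAs), in HEK-293T cells, a transformed human embryonic kidney line. It asked whether endogenous tRNA levels differ when a single guide RNA (sgRNA) for the nuclease Cas9 is made from a U6 promoter or from a tRNA promoter. Both promoters are read by RNA polymerase III, the enzyme that also makes the cell's own tRNAs. There were 3 libraries, with 1 library in each group. The first came from wild type cells, the next from a transduced polyclonal line with Cas9 and an sgRNA from the U6 promoter, and the last from a transduced polyclonal line with Cas9 and an sgRNA from a glutamine tRNA. With 1 library per group no difference has a replicate check, so no p-value is given, and each ratio compares libraries rather than conditions. Intervals in parentheses are exact 95% binomial (Clopper-Pearson) intervals unless stated otherwise. They cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

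The files listed 2299104 reads in the wild type library, 2835395 in the U6 library and 1998613 in the tRNAGln library. These were 69.2%, 80.5% and 69.9% of the library totals implied by the authors' scaling. Reads on features labelled as tRNA numbered 964115, 815087 and 954743, or 41.9% (41.9 to 42.0), 28.7% (28.7 to 28.8) and 47.8% (47.7 to 47.8) of the listed reads. The other large class was 5S ribosomal RNA, a small RNA of the large ribosomal subunit, with 30.1% of the listed reads in the wild type library, 55.9% in the U6 library and 28.8% in the tRNAGln library. Reads on tRNA lay on 421 features, grouped here into 59 families by amino acid and anticodon, with anticodons in DNA letters. Of these, 52 had an amino acid and a full anticodon. No feature was labelled as an initiator methionine tRNA or a mitochondrial tRNA, and the selenocysteine family had 1 read in the wild type library and 0 in the others.

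Reads of 15 or 16 nt made up 53.8% (53.7 to 53.9) of tRNA reads in the wild type library, 55.1% (55.0 to 55.2) in the U6 library and 65.2% (65.1 to 65.3) in the tRNAGln library. Full reads of 50 nt made up 0.725%, 1.63% and 1.68%, although the RNA had been selected at 50 to 140 nt. The share of tRNA reads that started at base 1 of the feature was 54.6% (54.5 to 54.7) in the wild type library, 68.1% (68.0 to 68.2) in the U6 library and 62.4% (62.3 to 62.5) in the tRNAGln library. A single interval, bases 1 to 16 of Leu-CAG, held 28.7% of all tRNA reads in the wild type library, 34.7% in the U6 library and 44.3% in the tRNAGln library. Fragments from base 1 to bases 30 to 36, the lengths of tRNA 5′ fragments cleaved in the anticodon loop, made up 5.66% (5.62 to 5.71), 13.8% (13.7 to 13.9) and 3.90% (3.86 to 3.94). Glycine families supplied 21.7% of these fragments in the wild type library, 59.0% in the U6 library and 52.4% in the tRNAGln library. The family values below therefore describe mostly short aligned stretches of tRNAs. These lie below the selected RNA sizes and the adapter trimming is not given, so whether the molecules themselves were short is not known.

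**Figure D1:**
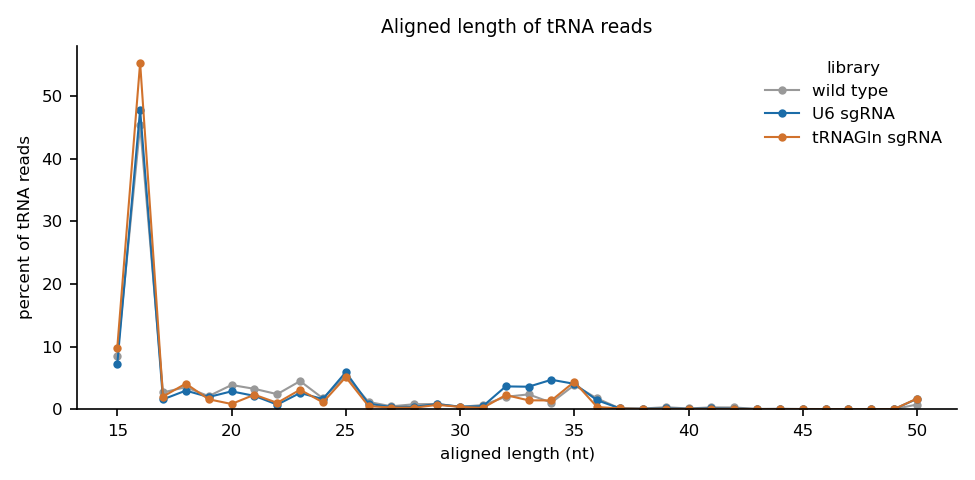
Aligned length in nt (x axis) against the percent of tRNA reads (y axis) in each of the 3 libraries, 1 line per library. Reads of 16 nt made up 45.3% of tRNA reads in the wild type, 47.9% in the U6 and 55.3% in the tRNAGln library.

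Leucine tRNAs were the most abundant group in each library, with 36.4% (36.3 to 36.4) of tRNA reads in the wild type, 37.7% (37.6 to 37.8) in the U6 and 46.4% (46.3 to 46.5) in the tRNAGln library. Glutamine tRNAs held 14.8% (14.8 to 14.9), 12.0% (11.9 to 12.1) and 15.2% (15.1 to 15.2). Lysine tRNAs held 13.0%, 14.6% and 12.8%. Glycine tRNAs held 2.06% (2.03 to 2.09), 9.14% (9.08 to 9.20) and 3.13% (3.09 to 3.16). Among 20 amino acids, glycine was the one whose sum differed by 2-fold or more between the tRNAGln and U6 libraries, where it was 2.92-fold lower (log2 ratio −1.55, −1.57 to −1.53). Proline came next, at 1.96-fold higher (log2 ratio 0.97, 0.88 to 1.07). With all listed reads as the total, glycine was 1.76-fold lower (−0.81) and 9 other amino acids, asparagine, glutamine, isoleucine, leucine, methionine, proline, threonine, tryptophan and tyrosine, were at least 2-fold higher. Leucine shares rest on the shortest reads. Among reads over 16 nt, leucine held 1.78%, 1.25% and 0.976% of tRNA reads, and glutamine held 23.8%, 22.1% and 31.5%.

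**Figure D2:**
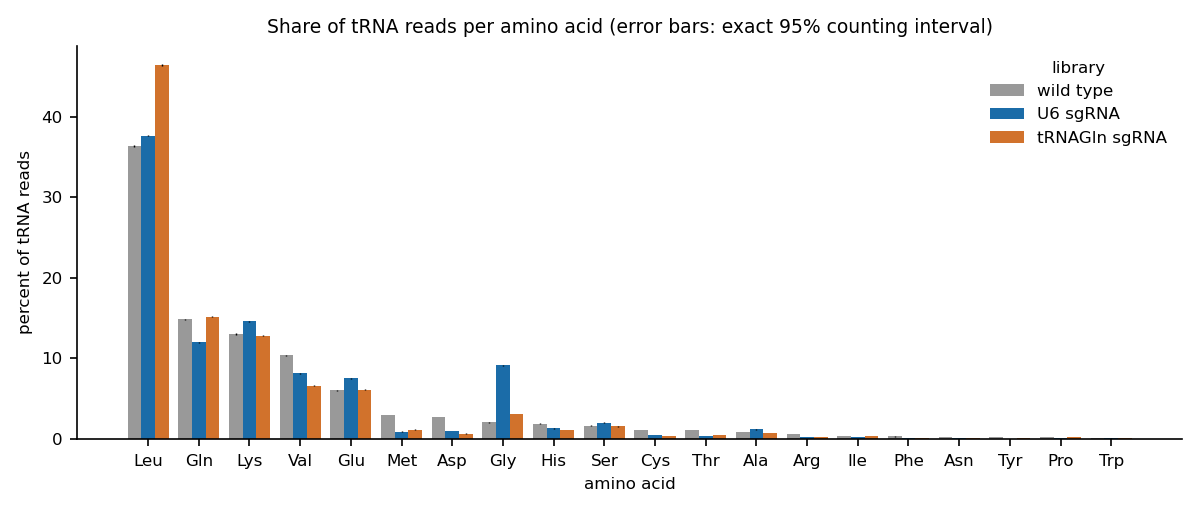
Percent of tRNA reads (y axis) for each of 20 amino acids (x axis), with 1 bar per library and exact 95% counting intervals as error bars. The glycine bar stands at 9.14% in the U6 library against 2.06% in the wild type and 3.13% in the tRNAGln library.

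The comparison of the tRNAGln with the U6 library addresses the question in the series title. Of 49 families with at least 100 reads over the 2 libraries, 37 lay within 2-fold, 5 were at least 2-fold higher in the tRNAGln library and 7 at least 2-fold lower. The higher families were Leu-AAG, Leu-CAA, Pro-TGG, Ala-TGC and Ser-TGA, and the lower families were Ser-AGA, Val-GAC, Leu-TAG, Gly-CCC, Ala-AGC, Gly-GCC and Glu-TTC. The median size of a family's difference was 1.51-fold (median absolute log2 ratio 0.60, 0.49 to 0.84 by resampling families). Levels across the 49 families correlated with Pearson's r = 0.87 and Spearman's rho = 0.85 on the log2 scale, a description across families, which are not independent replicates. The counting interval excluded 0 for 47 of the 49, so counting error was rarely the limit. With all listed reads as the total the median absolute log2 ratio was 1.05. With each distinct sequence counted once, 0 of 45 families differed by 2-fold or more and it was 0.14. Counts of distinct sequences respond less than reads, so the 2-fold rule is stricter for them. Thinning the reads of the higher library gave distinct sequences a median log2 ratio, signed by the reads, of 1.06 over the 11 measured differing families. It ranged from 0.51 for Ser-TGA to 3.31 for Ser-AGA.

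Leu-AAG was 15.3-fold higher in the tRNAGln library (log2 ratio 3.93, 3.83 to 4.04), with 14202 reads against 794. Of the 14202 reads, 12409 lay at bases 1 to 16, which do not reach the anticodon. Leu-CAA, whose human genes carry an intron, was 4.63-fold higher (log2 ratio 2.21, 1.69 to 2.78), from 190 reads against 35. Pro-TGG was 3.52-fold higher (log2 ratio 1.82, 1.66 to 1.98), Ala-TGC 2.58-fold (1.37, 1.2 to 1.5) and Ser-TGA 2.06-fold (1.04, 1.00 to 1.09). Ile-AAT (0.89), Val-AAC (0.86), Arg-CCG (0.84), Thr-AGT (0.75) and Arg-TCT (0.75) followed, all under 2-fold. Ser-AGA was 36.5-fold lower (log2 ratio −5.19, −5.35 to −5.03), with 325 reads against 10124. Val-GAC was 9.63-fold lower (−3.27, −3.32 to −3.21), Leu-TAG 6.26-fold (−2.65, −2.69 to −2.60) and Gly-CCC 5.69-fold (−2.51, −2.55 to −2.47). Ala-AGC was 2.82-fold lower (−1.50, −1.59 to −1.41), Gly-GCC 2.37-fold (−1.25, −1.27 to −1.22) and Glu-TTC 2.12-fold (−1.08, −1.11 to −1.06). Arg-ACG (−0.94), Ala-CGC (−0.90) and a family of unknown amino acid with the anticodon NTA (−0.85) were lower by less than 2-fold. Among the most abundant families, Leu-CAG stood at a log2 ratio of 0.35 and Glu-CTC at 0.49. Lys-CTT (−0.03) and Lys-TTT (−0.58) turned positive, at 0.70 and 0.15, when all listed reads set the scale.

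**Figure D3:**
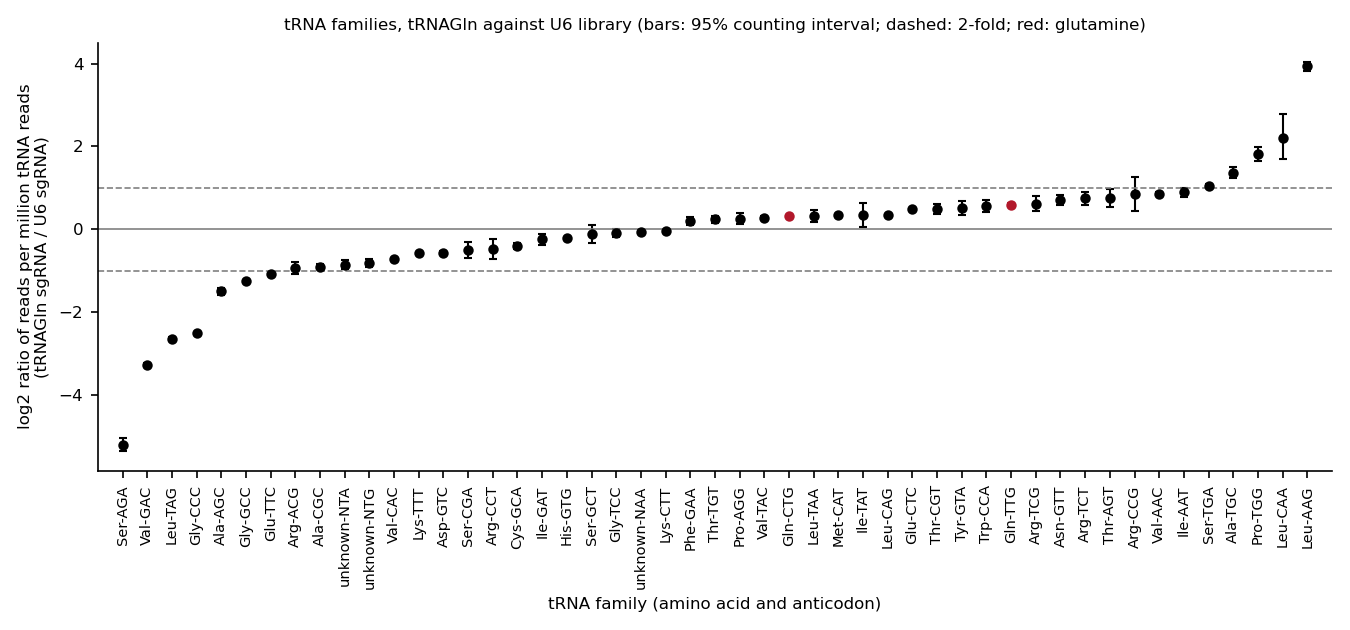
The log2 ratio of RPM of tRNA reads, tRNAGln over U6 library (y axis), for each of 49 tRNA families (x axis), with exact 95% counting intervals as bars, dashed lines at 2-fold and the glutamine families in red. The values run from −5.19 for Ser-AGA to 3.93 for Leu-AAG, and 37 families lie between the dashed lines.

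The choice of total moved all families together. The median log2 ratio over families was 0.25 with tRNA reads as the total, and it shifted by 0.73 with all listed reads, by 0.53 with the authors' library totals and by −0.12 with median-of-ratios factors. The split of higher against lower families was then 23 to 4, 17 to 4 and 4 to 9. With Leu-CAG left out of the total it was 8 to 6. Leu-AAG, Leu-CAA, Pro-TGG and Ala-TGC stayed at least 2-fold higher, and Ser-AGA, Val-GAC, Leu-TAG and Gly-CCC at least 2-fold lower, under each of these totals and under trimmed means of M-values. Ser-TGA, Ala-AGC, Gly-GCC and Glu-TTC kept their direction but not the 2-fold difference under at least 1 of them.

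Glutamine tRNAs are the kind whose gene drove the sgRNA in the tRNAGln line. Scaled to 1000000 tRNA reads, Gln-CTG had 139427 reads in the tRNAGln library, 112105 in the U6 library and 134705 in the wild type library. It was 1.24-fold higher in the tRNAGln than in the U6 library (log2 ratio 0.31, 0.30 to 0.33) and 1.04-fold higher than in the wild type library (0.05, 0.04 to 0.06). Gln-TTG was 1.51-fold higher than in the U6 library (0.60, 0.55 to 0.64) and 1.13-fold lower than in the wild type library (−0.18, −0.21 to −0.14). In the U6 library Gln-CTG was 1.20-fold lower than in the wild type library (−0.26, −0.28 to −0.25) and Gln-TTG 1.71-fold lower (−0.78, −0.82 to −0.73). Both families stayed higher in the tRNAGln than in the U6 library under each total tried, at 1.05 and 1.33 with all listed reads. Against the wild type library, Gln-TTG turned positive in the tRNAGln library and Gln-CTG turned positive in the U6 library under at least 1 other total. Reads of a vector copy with the same sequence are counted with the endogenous ones.

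Some single glutamine features moved far more than their families and others did not. How reads that match several features were placed is not known, so these counts need not follow single gene copies. Among 42 tRNA intervals with at least 1000 reads in both the tRNAGln and U6 libraries, the leading feature differed in 25. Among the Gln-CTG features, FR0033151 had 4071 reads in the wild type, 1866 in the U6 and 36719 in the tRNAGln library, while FR0371475 had 26935, 27092 and 7410, and FR0020599 had 9283, 13430 and 17302. Few reads of these families started at base 1, at 1.501%, 1.04% and 0.216% for Gln-CTG and 0.452%, 0.458% and 0.749% for Gln-TTG in the wild type, U6 and tRNAGln libraries. Bases 27 to 41 of Gln-CTG, around the anticodon, had 30907, 12850 and 31162 reads, and bases 21 to 55 had 18416, 16254 and 25109. Over all tRNA features with at least 100 reads over the tRNAGln and U6 libraries, 121 of 219 (55.3%) differed by 2-fold or more.

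Several family differences came from stacks of reads at 1 interval. For 9 of the 12 families that differed by 2-fold or more, another family of the same amino acid had an opposite difference of at least 2-fold at the same bases. Bases 1 to 16 of Ser-AGA had 794 reads in the wild type, 9310 in the U6 and 108 in the tRNAGln library, and the same bases of Ser-TGA had 8086, 826 and 10470. Their sums were 8880, 10136 and 10578, a log2 ratio of −0.17 between the tRNAGln and U6 libraries. Bases 1 to 16 of Leu-AAG had 58626, 243 and 12409 reads, those of Leu-TAG 5472, 18202 and 2082, and their sum a log2 ratio of −0.58. Bases 1 to 23 of Val-GAC had 73, 13452 and 89 reads, those of Val-AAC 26133, 194 and 20825, and their sum a log2 ratio of 0.39. Bases 1 to 19 of Ala-AGC and Ala-TGC likewise moved in opposite directions, with a sum at −0.84. At bases 56 to 70, Pro-TGG was higher and Pro-AGG lower in the tRNAGln library. Bases 1 to 16 were lower on Glu-TTC and higher on Glu-CTC. The sums for proline (1.32) and glutamate (−1.80) still differed by over 2-fold. No such opposite partner was found for Gly-CCC or Gly-GCC, and for Leu-CAA no other leucine family had enough reads at its bases to serve as a partner. The intervals and families in this paragraph were picked after their values had been seen.

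**Figure D4:**
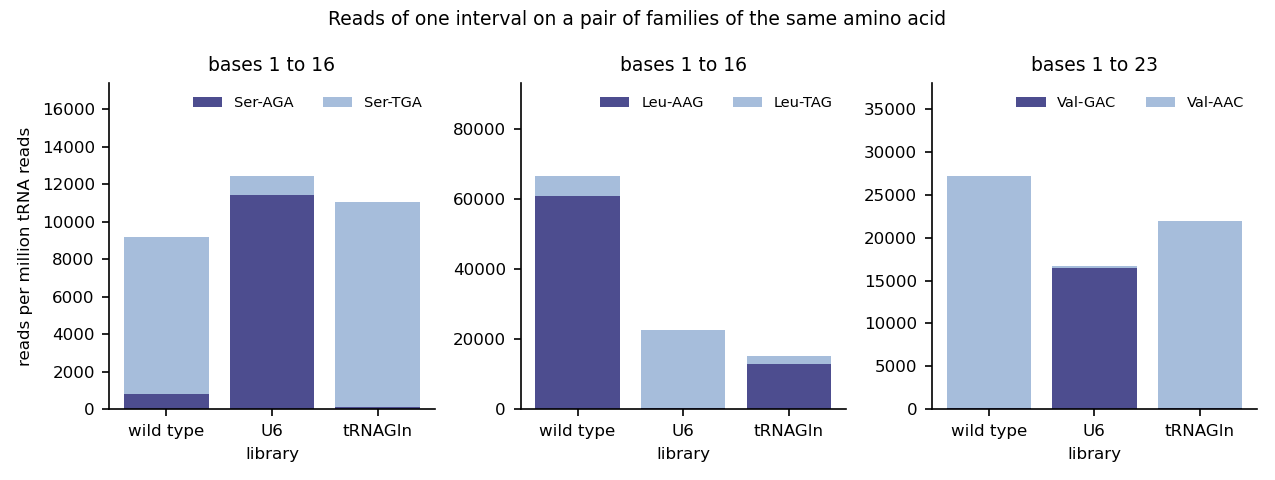
Reads scaled to 1000000 tRNA reads (y axis) at a single interval in the wild type, U6 and tRNAGln libraries (x axis), stacked for a pair of families of serine, leucine and valine. In the U6 library most reads sit on Ser-AGA (9310 reads), Leu-TAG (18202) and Val-GAC (13452), and in the tRNAGln library on Ser-TGA (10470), Leu-AAG (12409) and Val-AAC (20825).

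The lists of families fixed before the data were examined gave the following medians for the tRNAGln against the U6 library, some with their percentile among 10000 random lists of the same size matched on mean level. For the 2 glutamine families the median was 0.46, at percentile 88.7. For the 2 glutamate families it was −0.30, at percentile 36.8, with 1 family at least 2-fold lower, and it turned positive (0.44) with all listed reads as the total. Among 4 families with intron-containing genes (Arg-TCT, Ile-TAT, Leu-CAA and Tyr-GTA), 1 was at least 2-fold higher and the median was 0.63, at percentile 64.7. It was 1.36 with all listed reads, with 4 of the 4 at least 2-fold higher, 0.079 with distinct sequences and −0.038 among reads over 16 nt. Among 9 measured leucine and serine families, which have a long variable arm, 3 were at least 2-fold higher and 2 at least 2-fold lower. Their median was 0.32, at percentile 64.9, but their mean −0.07, and the median was −0.26 among reads over 16 nt. With all listed reads it was 1.05, with 5 higher and 2 lower. By amino acid, medians were negative for alanine (−0.90), aspartate (−0.57), cysteine (−0.40), glycine (−1.25), histidine (−0.21), lysine (−0.31), serine (−0.31) and valine (−0.22). All of these except alanine and glycine turned positive with all listed reads as the total. Medians were positive for arginine (0.62), asparagine (0.70), isoleucine (0.34), leucine (0.35), methionine (0.34) and phenylalanine (0.20), and for proline (1.04), threonine (0.49), tryptophan (0.57) and tyrosine (0.52). Among the lists of tRNA families, glycine had the lowest percentile (8.52) and glutamine the highest.

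The U6 library differed more widely from the wild type library, a comparison in which transduction, Cas9, the sgRNA and the promoter change together. Puromycin was also named for samples read here as the transduced lines. Of 51 families, 9 were at least 2-fold higher in the U6 library and 19 at least 2-fold lower. Ser-AGA was 8.13-fold higher (log2 ratio 3.02, 2.94 to 3.10), Gly-GCC 6.54-fold (2.71, 2.68 to 2.74) and Gly-CCC 4.56-fold (2.19, 2.15 to 2.23). The family with the anticodon NTG and no known amino acid was 3.12-fold higher (1.64, 1.53 to 1.76) and Leu-TAG 2.55-fold (1.35, 1.32 to 1.39), though under 2-fold with all listed reads (0.81). Leu-AAG was 62.9-fold lower (−5.98, −6.08 to −5.87), Arg-CCT 6.22-fold (−2.64, −2.81 to −2.46) and Thr-CGT 5.57-fold (−2.48, −2.58 to −2.37). The families labelled suppressor (−3.34) and pseudogene (−3.64) were also lower, from 54 and 8 reads in the U6 library. Families with intron-containing genes had a median of −1.87, at percentile 13.9, and 3 of 4 were at least 2-fold lower. Long-arm families had a median of −0.91 (−0.31 with median-of-ratios factors and −1.46 with all listed reads), glutamate families 0.26 (−0.28 with all listed reads) and glutamine families −0.52 (0.088 with median-of-ratios factors). The median absolute log2 ratio was 1.17 (0.90 to 1.44) and Pearson's r was 0.86. Other totals changed the split from 9 higher and 19 lower to 13 and 13 with median-of-ratios factors, 4 and 28 with all listed reads and 5 and 26 with the authors' totals. With each distinct sequence counted once, a measure that responds less than reads, 0 of 46 families differed by 2-fold or more. Bases 1 to 16 of Ser-AGA and Ser-TGA together had 8880 reads in the wild type and 10136 in the U6 library. Other pairs were less balanced, at 64098 and 18445 reads for bases 1 to 16 of Leu-AAG and Leu-TAG. Bases 1 to 23 of Val-GAC and Val-AAC had 26206 and 13646.

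Between the tRNAGln and wild type libraries, 5 of 51 families were at least 2-fold higher and 17 at least 2-fold lower. Arg-CCG was 4.04-fold higher (log2 ratio 2.01, 1.51 to 2.54), from 164 reads against 41. Gly-GCC was 2.76-fold higher (1.46, 1.43 to 1.501), Leu-CAA 2.46-fold (1.30, 0.91 to 1.70), Pro-AGG 2.12-fold (1.08, 0.93 to 1.23) and Ile-GAT 2.09-fold (1.06, 0.91 to 1.22). The last 2 rested largely on 1 interval each. Bases 56 to 72 of Pro-AGG had 658 reads in the tRNAGln and 48 in the wild type library, while those of Pro-TGG had 89 and 1036. Bases 38 to 52 of Ile-GAT had 845 and 178. These intervals were picked after their values had been seen. Val-GAC was 9.10-fold lower (−3.19, −3.24 to −3.13), Arg-CCT 8.64-fold (−3.11, −3.30 to −2.92) and Ser-CGA 5.75-fold (−2.52, −2.67 to −2.38). The suppressor (−4.28) and pseudogene (−2.17) families were lower from 33 and 26 reads. Long-arm families had a median of −1.29 and intron-containing families −1.31, with 3 of the 4 at least 2-fold lower. With median-of-ratios factors these medians were −0.81 and −0.83, with 0 of the 4 intron-containing families at least 2-fold lower, and with all listed reads −1.11 and −1.12, with 2 of the 4. Glutamate families had a median of −0.03 and glutamine families −0.06, and both turned positive with all listed reads (0.16 and 0.12). The median absolute log2 ratio was 0.80 (0.52 to 1.29) and Pearson's r was 0.90. With median-of-ratios factors 8 families were higher and 11 lower. With each distinct sequence counted once, a measure that responds less than reads, 1 of 46 was higher and 1 lower.

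With the other pairs of libraries as the available yardstick, the tRNAGln and U6 libraries lay closer together in the size of family differences than the U6 and wild type libraries. The difference in median absolute log2 ratio was −0.52 over 49 families (−0.80 to −0.17 by resampling families). With all listed reads it was −0.39, and its interval (−0.72 to 0.19) included 0. The difference from the pair of tRNAGln and wild type was −0.20, and its interval (−0.58 to 0.23) included 0. That difference turned positive with all listed reads (0.38, −0.14 to 0.66) and with the authors' totals (0.20, −0.28 to 0.47), so which of these pairs lay closer depends on the total. Families are not replicates, so these intervals describe the 3 libraries.

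Most other RNA polymerase III transcripts were lower relative to tRNA in the tRNAGln library. Of 7 with enough reads in the comparison with the U6 library, 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median of −1.25, at percentile 0.240 among labels other than tRNA. On the authors' totals 1 of the 7 was at least 2-fold lower (median −0.72), and with all listed reads 0 were (median −0.51). On the authors' totals 5S ribosomal RNA was 2.23-fold lower in the tRNAGln than in the U6 library, at 201535 against 449947 RPM (reads scaled to 1000000 of the library total), and the wild type library had 208025. Y RNA, a component of Ro particles, stood at 7084 RPM in the wild type, 3785 in the U6 and 2067 in the tRNAGln library. The 7SK RNA, a regulator of transcription elongation, stood at 124 RPM in the wild type, 83.2 in the U6 and 115 in the tRNAGln library, with a log2 ratio between the tRNAGln and U6 libraries of 0.47 on this scale and −0.06 (−0.29 to 0.18) relative to tRNA. The U6 spliceosomal RNA had 293, 174 and 72 reads. Against the wild type library, the median of this list was −1.56 in the tRNAGln library, where 7 of 9 were at least 2-fold lower (5 of 9 with all listed reads, the authors' totals or median-of-ratios factors), and −0.51 in the U6 library, which turned to 0.099 with median-of-ratios factors.

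Among 104 labels of small nucleolar, Cajal body and spliceosomal RNAs made by RNA polymerase II, 24 were at least 2-fold higher in the tRNAGln than in the U6 library and 18 at least 2-fold lower, relative to tRNA reads. Their median was 0.24, and it turned negative among reads of at least 30 nt (−0.57), with distinct sequences (−0.058) and with a minimum of 1000 reads (−0.0081). With all listed reads the counts were 49 higher and 8 lower, and with median-of-ratios factors 19 and 20. Spliceosomal U1 RNA was lower relative to tRNA in the tRNAGln than in the U6 library (−1.05, −1.13 to −0.97), as was U2 RNA (−1.13, −1.21 to −1.05). On the authors' totals these ratios were −0.52 and −0.60. U5 RNA was lower still (−2.86, and −2.34 on the authors' totals), from 49146 reads in the U6 and 7902 in the tRNAGln library, and U4 RNA stood at −0.03 (−0.39 to 0.33), or 0.50 on the authors' totals. These labels were singled out after their values had been seen. Against the wild type library the list's median was −0.90 in the U6 library and −0.63 in the tRNAGln library, with 59 of 128 and 55 of 133 labels at least 2-fold lower. With median-of-ratios factors these were 27 and 39, and with all listed reads 87 and 46. As for tRNAs, these labels can share reads with near-identical copies.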

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

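The tests of the partner stacks, the promoter and the lengths of other RNAs against the tRNAGln library were chosen after the result was seen, and the counts of distinct sequences and the lengths of other RNAs against wild type were planned before theirs were computed. The thinning of reads was added after the distinct sequences had been counted, and the random draws were narrowed to families with reads at the same bases after a first, wider draw.

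Ser-AGA and Leu-TAG moved in opposite directions from wild type in the transduced lines. Ser-AGA had a log2 ratio of 3.02 in the U6 library and −2.17 in the tRNAGln library, and Leu-TAG had 1.35 and −1.29. With 1 library per group the difference between the lines was not tested. Both are among the 12 families that differed by 2-fold or more between the tRNAGln and U6 libraries.

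For 9 of those 12 families the leading sequence met an opposite difference of at least 2-fold on another family of the same amino acid, against a median of 3 and a maximum of 6 in 2000 random draws from families of other amino acids with reads at the same bases, which fits a sequence shared by families of one amino acid counted on different families in different libraries. The 9 are not independent, since pairs such as Ser-AGA with Ser-TGA count from both sides. For Pro-TGG and Glu-TTC the pair sums still differed by over 2-fold (1.32 and −1.80), so the opposite moves did not balance there. That partners share the sequence was not checked, as no feature sequences were at hand. With each distinct sequence counted once, the median log2 ratio of the 11 measured families, signed by the direction of the reads, was 0.13 (0.03 to 0.26), below the 1.06 that thinning the reads of the higher library gave, so the differences may rest on large stacks, through placement, amplification or particular fragments. Without the largest sequence of each family in each library, 7 of the 12 stayed past 2-fold. What was left out could differ between libraries. For Val-GAC the leading interval was bases 1 to 23 in the U6 and bases 21 to 36 in the tRNAGln library. This setting therefore cannot decide whether a single stack is the whole account. An effect of the promoter cannot be told apart from differences between cultures or libraries, each promoter having 1 library, and the median absolute log2 ratio between the promoters minus that between the U6 and wild type libraries was −0.52 (−0.80 to −0.17).

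Fragments from base 1 to bases 30 to 36 were more frequent in the U6 library (13.8% of tRNA reads) than in the wild type (5.66%) or tRNAGln library (3.90%). Against wild type, longer inserts of all RNAs in the U6 library predict longer ribosomal subunit and small nucleolar RNA reads. Their share at 30 to 36 nt was instead lower in the U6 library, at 6.62% against 9.51% (log2 ratio −0.52, −0.57 to −0.48). The make-up of this pool changed, however. Small subunit reads numbered 18806 in the wild type and 36110 in the U6 library, and large subunit reads 53120 and 31364. The pooled share thus mixes composition with length and cannot decide the question. Over all RNAs, reads of 15 or 16 nt were fewer in the U6 library, at 23.4% against 36.5%. Those shares include 5S ribosomal RNA, at 55.9% against 30.1% of listed reads, so they mix composition with length. Longer aligned reads of all RNAs may account for part of the difference from the tRNAGln library, with the same limit of a pool that changes in make-up. The share of 30 to 36 nt in ribosomal subunit and small nucleolar RNAs was 3.13% there, a log2 ratio of 1.08 (1.02 to 1.14) against 1.82 for the tRNA fragments. Glycine families made up most of the excess over wild type, at 8.14% of tRNA reads in the U6 and 1.23% in the wild type library, against 5.66% and 4.44% for all other families together. A difference in tRNA cleavage between the lines and a difference between single libraries both stay open, and neither was tested. RNA of 50 to 140 nt was selected, which should have removed most cellular fragments of 30 to 36 nt. At which step these fragments arose is not known.

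Reads labelled mir-565, a microRNA label outside the comparisons above, were higher in the tRNAGln than in the wild type library by a log2 ratio of 1.46 on the authors' totals. The label was picked after its values had been seen. There were 28018 reads in the wild type, 35843 in the U6 and 66157 in the tRNAGln library. Bases 59 to 73 held 77.6%, 29.3% and 43.7% of them. Whether these short reads came from a microRNA or from another RNA, such as a tRNA, was not checked.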

How the results depend on the processing

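Amino acid sums, the authors' totals, the families without their largest sequence and reads over 16 nt were chosen after seeing the data. Values are tRNAGln against U6 unless stated, and the cause of a change was not tested. Median-of-ratios factors gave log2 ratios of 0.19 for Gln-CTG and 0.48 for Gln-TTG, and trimmed means of M-values 0.25 and 0.54. All listed reads gave 27 differing families, a median absolute log2 ratio of 1.05, glutamine ratios of 1.05 and 1.33, and list medians of −0.51 for other polymerase III and 0.97 for polymerase II small RNAs. Each distinct sequence counted once, a measure that responds less than reads, gave 0 differing families, 0 for U6 and 2 for tRNAGln against wild type. The median absolute ratio was then 0.14, r 0.98, glutamine ratios 0.050 and 0.12, and list medians 0.079 (intron-containing), −0.71 (polymerase III) and −0.058 (polymerase II). In the wild type, U6 and tRNAGln libraries leucine held 5.56%, 4.47% and 5.11%, glutamine 10.9%, 14.6% and 15.3% and starts at base 1 18.0%, 25.2% and 17.8% of distinct sequences. Reads of at least 30 nt gave 10 differing families out of 18 measured, and 15 out of 23 for U6 against wild type. The median absolute ratio was 1.11, with glutamine ratios of 1.18 and 1.33 and a polymerase II median of −0.57. Leucine then held 0.221%, 0.0319% and 0.0318%, glutamine 32.9%, 19.4% and 44.5% and starts at base 1 44.7%, 69.0% and 32.5%. Single features gave 121 differing units, 169 for U6 and 168 for tRNAGln against wild type. A rule of 1.5-fold gave 26 families. Without Leu-CAG in the total, glutamine ratios were 0.54 and 0.83 and the polymerase II median 0.47. Amino acid sums, with the suppressor, pseudogene and unknown labels kept as groups of their own, gave 1 differing group of 21 measured. They gave 10 of 23 for U6 and 8 of 23 for tRNAGln against wild type. Among the 20 amino acids alone these counts were 1, 8 and 6. The median absolute ratio of the groups was 0.36 and r 0.98. The authors' totals gave 21 families, a median absolute ratio of 0.87, glutamine ratios of 0.84 and 1.13, and list medians of −0.72 and 0.77. Without the largest sequence of each family there were 17 differing families for U6 against wild type, r was 0.94, Gln-CTG 0.24 and the intron-containing median 0.31. Reads over 16 nt gave 17 differing families out of 47 measured, glutamine ratios of 0.46 and 1.06 and an intron-containing median of −0.038. Leucine was then at 1.78%, 1.25% and 0.976%, glutamine at 23.8%, 22.1% and 31.5% and starts at base 1 at 26.3%, 41.7% and 23.1%. Minimums of 10, 1000 and no reads kept the counts of differing families within 1.5 times the main values, at 13, 11 and 14 against 12. Of the 12 differing families, all 12 kept their direction with other totals, and 11 of 11 measured among reads over 16 nt, where 8 stayed past 2-fold. Among reads of at least 30 nt 4 of the 12 were measured, and 2 stayed past 2-fold. Of the 11 measured with distinct sequences, 9 kept their direction. Alignments without mismatches and reads with a single matching feature were not run, since the files record neither. No replicate could be left out. Depth limits the families with few reads, such as Leu-CAA (35 and 190 reads), and not the abundant ones.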

Other observations

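The test of a vector copy was chosen after the glutamine values had been seen.

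The tRNA-derived 5′ fragments ending at bases 30 to 36 came largely from glycine families in the U6 and tRNAGln libraries and were spread more widely in the wild type library. Gly-GCC supplied 10.4% of them in the wild type, 35.7% in the U6 and 40.8% in the tRNAGln library, and Gly-CCC 10.3%, 23.1% and 11.5%. Asp-GTC supplied 15.8% in the wild type library but 2.32% and 2.87% in the U6 and tRNAGln libraries. Val-GAC supplied 15.1%, 4.12% and 1.81% in the wild type, U6 and tRNAGln libraries, and Val-AAC 14.0%, 8.96% and 2.90%. Lys-CTT supplied 9.57%, 13.7% and 29.0%. In the U6 library 95.2% of Gly-CCC reads and 87.7% of Gly-GCC reads were such fragments, against 79.5% and 68.7% in the wild type library. For Val-AAC this share was 19.4% in the wild type, 76.7% in the U6 and 3.85% in the tRNAGln library. The Val-AAC fragments numbered 7654, 10084 and 1080, while its reads at bases 1 to 23 numbered 26133, 194 and 20825. The share of this family therefore also follows that stack, whose reads moved oppositely on Val-GAC.

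Some small nucleolar RNAs, which guide RNA modification, differed between the libraries by more than most tRNA families. These 3 were picked after their values had been seen. SNORD49A had 1169 RPM on the authors' totals in the wild type, 1641 in the U6 and 4786 in the tRNAGln library. SNORD16 had 624, 23.3 and 5.60, and SNORA65 had 893, 406 and 66.8. Reads labelled as piRNA made up 11.6%, 5.25% and 9.37% of listed reads in the same order. Labels of human immunodeficiency virus elements, which lentiviral vectors carry, had few reads. The Rev response element had 0 reads in the wild type, 2 in the U6 and 5 in the tRNAGln library, and the primer binding site had 4, 15 and 1.

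Large stacks on 5S ribosomal RNA sat on a different feature in each library. Bases 1 to 39 held 298175 reads in the wild type, 1007458 in the U6 and 386087 in the tRNAGln library. Of these, 95.8% lay on FR0389950 in the wild type, 94.1% on FR0328418 in the U6 and 95.4% on FR0139174 in the tRNAGln library, and each of these features held under 2% in the other libraries. Among 42 tRNA intervals with at least 1000 reads in both the tRNAGln and U6 libraries, the leading feature of the family differed in 25 (59.5%, 43.3 to 74.4). These features were singled out after their values had been seen.

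Glutamine tRNA reads were higher in the tRNAGln than in the U6 library, and reads of a vector copy of the tRNA are a candidate explanation. The glutamine families lay between percentile 55.1 and 73.5 among families in the comparisons with the U6 and wild type libraries. That is above the middle in each and short of the 90th percentile set for a copy that stands out. A small contribution and none cannot be told apart, because the reads carry no mark of their origin and the wild type and U6 libraries differ from each other in the same families.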
